A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

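Total RNA of 10 yeast cultures, 5 naive and 5 [BIG+], was sequenced after rRNA depletion. Per the labels' protocols, independent colonies of BY4741 were grown in 5 mL starter cultures and then in 700 mL of rich medium at 30 °C to an OD of 1.0. By the same protocols, RNA was treated with RiboZero, and libraries were made and sequenced at an outside institute. The authors deposited 1 table of TPM values, normalized within each library to a fixed sum. Per the submitters' processing notes, Bowtie2 and HTSeq were used with genome build R64; their versions, the annotation release and the use of strand in counting are not given in the sources used here. Values of overlapping, antisense and near-identical genes are therefore uncertain, among them SPS100 (which overlaps SUT169), IRC9 (YAK1), YGL088W (snR10), snR191 (NOG2), and the copies of CUP1 and rDNA. A related dataset with spike-in controls was not analysed here.

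The table held 7032 features, of which 577 were at 0 in all libraries; 4 emptied lines were left out. By the type the table gives, 6596 features were mRNAs, of which 5914 matched an R64 locus tag in the reference table. All 299 tRNA features were at 0, and no retrotransposon feature was present, so these classes were not tested. TPM keeps no sequencing depth and its values do not step in whole reads, so depth is unknown, and no counting interval or floor is given.

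Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), over the 5732 genes with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit held the 2 states and no block. Gene lists, 41 in number, were tested against all other genes with limma's camera at a preset correlation of 0.01 if at least 3 members were tested, which left 40; the list of alpha-cell genes had 2. Alternatives were an estimated correlation and fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The names ARG5,6, DUR1,2, MFALPHA1 and MFALPHA2 were not matched in the table. Members of a list were also adjusted over that list alone, which does not correct across the 40 lists. A member that passes only in this way is not called over all genes. Pseudouridine synthase and marker genes, chromosome medians and class shares were tested by two-sided exact permutation over all 252 assignments of the libraries (smallest p 0.00794), and within pairs over 32 (smallest p 0.0625). After adjustment a gene, chromosome or class changed alone could therefore not pass (smallest adjusted p 0.0873, 0.127 and 0.0635). Differences are [BIG+] minus naive throughout, errors of levels are SD and errors of fold changes are SE. Python (3.11.15), with pandas (2.3.3) and matplotlib (3.10.9), was used for tables and figures.

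The tests, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The groups share replicate numbers 1 to 5, which the labels do not state to be shared days or batches. Deviations from the group means correlated between same-numbered libraries at 0.74, 0.57, 0.53, 0.35 and 0.47. Each was above 0.1, so the numbers were taken to pair the samples. The fit with the replicate block is given beside results whose call it changes. In both states, however, replicate 2 was closest to replicate 1 of the other state, and replicate 4 to replicate 3. The correlations therefore cannot tell pairing by number from the sets of numbers given next. Correlations were at least 0.35 within the sets of replicates 1 and 2, 3 and 4, and 5, and at most 0.31 between them. A block by these sets was added after the data were seen, as were the alternatives applied to the paired fit and the fits without [BIG+] replicate 5.

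Named genes were the pseudouridine synthases and marker genes; up to 15 genes each way with the largest change among those past the threshold with a mean of at least 10 TPM and no overlap between the states; and up to 3 members of each list past the threshold, or its most abundant member. Without the block no gene passed, so the same rule applied to the paired fit gave 15S rRNA, YCL048W-A, GSC2, YGP1, HSP12, SPI1, SPS100, MET6, PHO89, FET3 and SED1. Other named members of lists, snoRNAs, rRNA features and YHR054C were chosen after their values were seen.

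The steps were tested on simulated data for the 5732 genes of this comparison. Of 50 genes changed by 0.5, 1, 1.5 or 2 on the log2 scale, 2, 72, 90 and 96% were recovered without the block, with 0 false calls, and 78, 98, 96 and 100% with the replicate block, with 9 false calls. With the block by sets 64, 98, 96 and 100% were recovered, with 1 false call. The simulation gave same-numbered libraries a shared replicate effect and independent residuals, so the gain with the replicate block was built in. These counts therefore do not test whether the numbers pair the real samples. Among 40 simulated lists of 30 genes, the list shifted by 0.5 was called in both fits and 0 others were. These lists held random genes with independent residuals, whereas estimated correlations of the real lists ran from 0.056 (stationary phase) to 0.899 (chaperones). The 0 other calls therefore say nothing about false calls among the real lists. An extra chromosome copy was recovered as 0.99 but not called (exact permutation, adjusted p = 0.0635). That value lies below the 0.127 of a chromosome changed alone, which takes small p values at other chromosomes too. Alternatives covered the pseudocount (0.1 or 10), the filter (none or a mean of at least 10 TPM), scaling (median of ratios, nuclear mRNA, quantile), the variance model, a fold threshold, the block, the set test and each library or pair left out.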

Results

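The series compared naive cells of BY4741, a haploid laboratory strain of budding yeast, with cells of the same background that carry the prion [BIG+], a heritable state passed on through a protein. Each state had 5 libraries of rRNA-depleted total RNA, which the labels describe as independent colonies, so the spread between replicates is one between separate cultures. The labels give all naive libraries a common name stem and all [BIG+] libraries another. If these stems are strains, other differences between the strains cannot be told apart from the prion state. The authors deposited transcript levels as TPM, which keep no sequencing depth, so the number of reads behind a value is unknown. Library totals ran from 999963 to 999982 TPM, and between 6241 and 6325 features were above 0 in a library. Libraries resembled each other by sets of replicate numbers more than by prion state. They fell into samples numbered 1 and 2 (4 samples), 3 and 4 (4 samples), and 5 (2 samples), and each of the 10 libraries was closest to one of its own set. Values are given without and with the replicate number as a block, the latter called the paired fit, wherever the block changes a call.

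**Figure D1:**
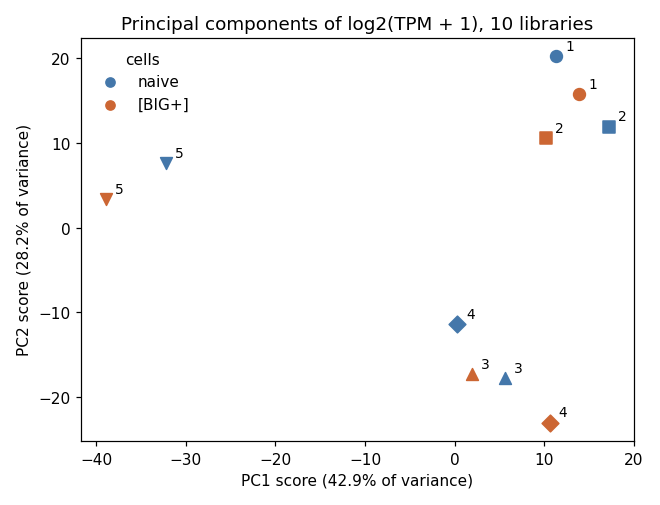
First and second principal components of log2(TPM + 1) values of the tested genes for the 10 libraries, 1 point per library, with the percent of variance on each axis. The first component (42.9%) sets both replicate 5 libraries apart and the second (28.2%) parts replicates 1 and 2 from 3 and 4, while the prion states lie side by side.

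The question was which transcripts differ between prion-containing and naive cells. HSP12, a small stress-induced membrane-associated protein (YFL014W, chromosome VI, 107256 to 107585, R64), averaged 432 ± 241 TPM in naive cells and 114.5 ± 61.7 TPM in [BIG+] cells (SD, n = 5 each), and was lower in [BIG+] in 5 of 5 pairs. GSC2, a catalytic subunit of the cell wall glucan synthase (YGR032W, chromosome VII, 548264 to 553951), averaged 32.6 ± 3.08 TPM and 16.8 ± 1.89 TPM, with no overlap between the states. Both fell in the paired fit, HSP12 by 1.89 ± 0.117 and GSC2 by 0.917 ± 0.093 (SE) on the log2(TPM + 1) scale, which understates the change of low genes. Their limma adjusted p values were 0.000102 and 0.00412. Over the 15 alternatives of the paired fit these ran from 1.16e-06 to 0.00156 for HSP12 and from 0.000294 to 0.0323 for GSC2. Among these alternatives the fold threshold of 1 (log2) leaves the adjusted p unchanged, here and in the ranges below. HSP12 reaches that threshold and GSC2 does not. Without the block neither passed (adjusted p = 0.237 and 0.15).

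Over all 5732 tested genes, limma without the block called 0 genes higher and 0 lower, with 96 at an unadjusted p under 0.05 (14 higher, 82 lower) where chance gives 287. The paired fit called 2 genes higher and 33 lower, with 650 at an unadjusted p under 0.05. All 35 moved in 1 direction in 5 of 5 pairs, which the paired fit favours when it picks genes. Of all 5662 tested mRNAs, 560 were lower in [BIG+] in 5 of 5 pairs. The 33 lower features were 20 mRNAs (among them YGL088W, which overlaps snR10) and 13 snoRNAs. The 2 higher ones were the mitochondrial 15S rRNA and YHR054C. Leaving out 1 pair moved the paired counts to 1 higher and 15 lower without replicate 1, 1 and 13 without replicate 2, 2 and 8 without replicate 3, 1 and 17 without replicate 4, and 9 and 26 without replicate 5. Median-of-ratios scaling gave 1 higher and 13 lower in the paired fit, and quantile normalization 1 and 17. The median log2 fold change over all tested genes was -0.057, and 0.003 and 0.001 under these scalings. Groups did not overlap at 22 genes (15 lower, 7 higher), where chance gives 45, a share of 0.794%.

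Of 45 tested general stress genes 34 were lower in [BIG+], where 3754 of all 5662 tested mRNAs were, with a mean log2 fold change of -0.25, and 3 fell in the paired fit (10 adjusted over the list alone; without the block 0, and 1 adjusted over the list alone). Besides HSP12 these were YGP1, a secreted glycoprotein (YNL160W, chromosome XIV, 336545 to 337609), at 99.6 ± 25.7 and 58.6 ± 12.5 TPM, and SPI1, a cell wall protein (YER150W, chromosome V, 468370 to 468816), at 28.9 ± 12.6 and 16.7 ± 6.97 TPM. Their log2 fold changes were -0.752 ± 0.133 and -0.754 ± 0.116 (SE; adjusted p = 0.041 and 0.0215 in the paired fit, limma). Among the members that passed over the list alone, CTT1, the cytosolic catalase, averaged 5.27 ± 4.16 and 2.51 ± 0.858 TPM, and DDR2, a DNA damage and stress response gene, 98.3 ± 62.7 and 56.9 ± 15.2 TPM. The list was lower by camera (adjusted p = 0.00106, paired 0.000966; adjusted p = 0.948 with an estimated correlation, 0.82 paired). Its mean was -0.774 in pair 5 against -0.251 to -0.063 in the other 4 pairs, and the call was lost without naive replicate 5 (adjusted p = 0.382), with replicate sets as the block and [BIG+] replicate 5 left out (0.0799) and, paired, without replicate 5 (0.159). YGP1 lost its call without replicate 2, 3, 4 or 5 (0.0788, 0.128, 0.11 and 0.066) and SPI1 without replicate 2, 3 or 4 (0.072, 0.106 and 0.0703). Over the 15 alternatives of the paired fit their adjusted p ran from 0.00701 to 0.128 and from 0.00375 to 0.106.

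Cell wall genes were lower in 20 of 25 cases (mean log2 fold change -0.20), and 2 fell in the paired fit, GSC2 and SED1 (4 adjusted over the list alone; without the block 0, and 1, GSC2, adjusted over the list alone). SED1, a major structural protein of the wall (YDR077W, chromosome IV, 600793 to 601809), averaged 509 ± 171 TPM in naive and 336 ± 113 TPM in [BIG+] cells, a log2 fold change of -0.601 ± 0.104 (SE; limma adjusted p = 0.0401, paired). The other members that passed over the list alone were CWP1 and HSP150, both wall mannoproteins, with log2 fold changes of -0.54 ± 0.139 and -0.353 ± 0.09. The list's camera adjusted p was 0.00171 and 0.00178 with the block (adjusted p = 0.948 with an estimated correlation, 0.82 paired), and no left-out library or pair ended the call. SED1 did not pass without replicate 1, 2, 3, 4 or 5 (adjusted p between 0.059 and 0.137; 0.0117 to 0.137 over the 15 alternatives).

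Stationary-phase markers were lower in 8 of 9 cases, with a mean log2 fold change of -0.29. SPS100, a spore wall maturation protein (YHR139C, chromosome VIII, 378219 to 379199), fell in the paired fit from 2.06 ± 0.669 to 0.748 ± 0.101 TPM. Its log2 fold change was -0.786 ± 0.103 (-1.31 with a pseudocount of 0.1 and -0.165 with 10; limma adjusted p = 0.012; 0.00184 to 0.0655 over 14 alternatives, the highest without replicate 3). Adjusted over the list alone, 3 members fell (SPS100, HBT1, FMP16) and 1 rose, HSP30, at 46.8 ± 23.1 and 62.1 ± 34.4 TPM; without the block 1 fell, SPS100. Camera gave an adjusted p of 0.00193 (0.0407 paired; adjusted p = 0.628 with an estimated correlation, 0.82 paired). The call was lost without [BIG+] replicate 5 (0.133) and, paired, without replicate 2, 3 or 5 (0.369, 0.0981 and 0.0716). The paired call was also lost with a pseudocount of 10 (0.102) and with no filter on low values (0.143).

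**Figure D2:**
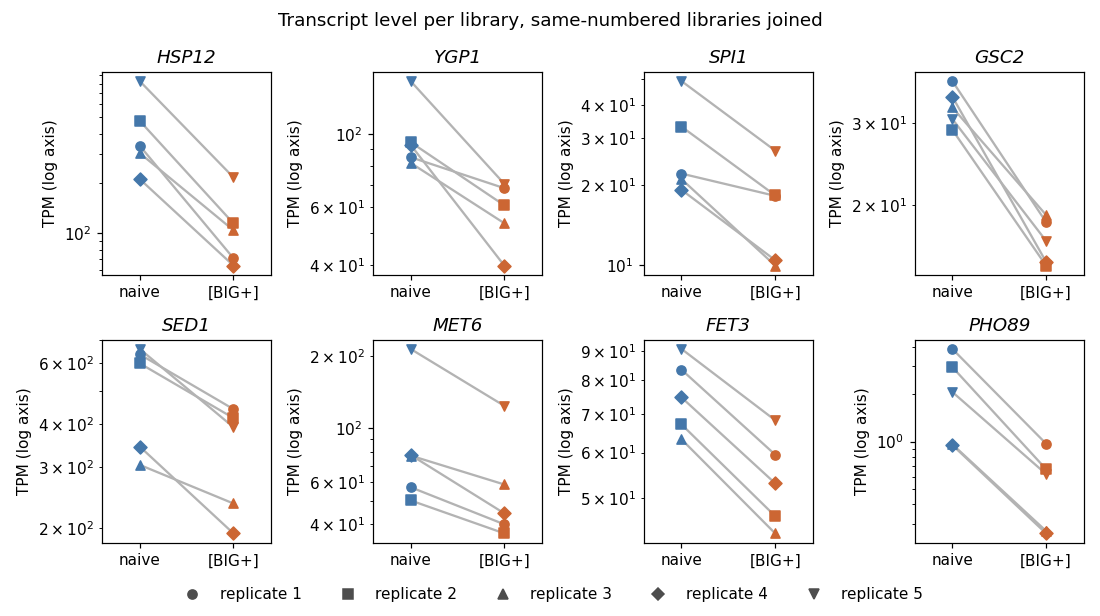
TPM on a log axis of 8 genes that fell in the paired fit (HSP12, YGP1, SPI1, GSC2, SED1, MET6, FET3 and PHO89) in the 10 libraries, with points for single libraries joined by replicate number. Each of the 8 genes was lower in [BIG+] in 5 of 5 pairs, which the paired fit that picked them favours.

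Most tested genes of phosphate and iron acquisition were lower in [BIG+] cells, where 3754 of all 5662 tested mRNAs were. Neither list passed with an estimated correlation or with fry. All 16 tested genes of the phosphate starvation regulon had negative log2 fold changes (mean -0.29), and of 17 iron regulon genes 16 did (mean -0.26); both list means were lower in 5 of 5 pairs. PHO89, a sodium-coupled phosphate transporter (YBR296C, chromosome II, 796798 to 798522), fell in the paired fit from 2.16 ± 1.27 to 0.560 ± 0.299 TPM, a log2 fold change of -0.944 ± 0.12 (-1.702 with a pseudocount of 0.1 and -0.198 with 10; limma adjusted p = 0.0116; 0.00128 to 0.0491 over 14 alternatives). FET3, the ferroxidase of high-affinity iron uptake (YMR058W, chromosome XIII, 388822 to 390732), fell from 75.8 ± 11.3 to 54.2 ± 9.98 TPM, a log2 fold change of -0.483 ± 0.087 (adjusted p = 0.0436; 0.0117 to 0.217 over 15 alternatives). Paired and adjusted over the list alone, 7 phosphate genes fell (1 over all genes; without the block 0 over all genes and 1 over the list alone). Among them were the acid phosphatases PHO5, PHO11 and PHO12, with log2 fold changes of -0.301 ± 0.088, -0.405 ± 0.12 and -0.363 ± 0.1. PHO11 and PHO12 are near-identical copies whose values are uncertain. Paired and adjusted over the list alone, 10 iron genes fell (1 over all genes, and without the block 0 by either adjustment). They included the siderophore transporters SIT1 and ARN1, with log2 fold changes of -0.575 ± 0.121 and -0.388 ± 0.098, and the ferric reductase FRE1, at -0.483 ± 0.105. Over all genes these did not pass either (paired limma adjusted p = 0.0949, 0.177 and 0.105). PHO84, the most abundant phosphate gene, averaged 361 ± 135 and 330 ± 136 TPM (limma adjusted p = 0.999, paired 0.664).

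Camera gave an adjusted p of 1.08e-05 for the phosphate list (6.88e-06 paired; adjusted p = 0.725 with an estimated correlation, 0.68 paired). For the iron list it was 0.000156 (6.88e-06 paired; adjusted p = 0.948 with an estimated correlation, 0.68 paired). With fry the adjusted p values were 0.735 for the phosphate list and 0.998 for the iron list (0.0738 paired for each). No left-out library or pair ended either camera call. FET3 did not pass without replicate 1, 2, 3, 4 or 5 (adjusted p between 0.0599 and 0.217), whereas PHO89 passed without each.

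Further nutrient lists were lower by smaller amounts. MET6, the methionine synthase (YER091C, chromosome V, 339864 to 342167), fell in the paired fit from 95.1 ± 67.4 to 60.7 ± 36.4 TPM (log2 fold change -0.581 ± 0.101; limma adjusted p = 0.041, 0.00818 to 0.137 over 15 alternatives). Of 21 methionine and sulfur genes 17 were lower (mean -0.165), of which 1 passed over all genes and 2 adjusted over the list alone, MET6 and the methionine permease MUP1. Of 14 gluconeogenic genes 13 were lower (mean -0.153; 0 fell over all genes, 1, the regulator ADR1, adjusted over the list alone). The nitrogen catabolite genes (13 of 15 lower, mean -0.152) and nutrient signalling regulators (24 of 28, mean -0.118) had 0 members past the threshold in either adjustment. Paired camera gave adjusted p values of 0.0265, 0.036, 0.0215 and 0.0153 for these 4 lists. Without the block the values were 0.0598, 0.0617, 0.0155 and 0.03, so the methionine and gluconeogenic calls held only with the block (adjusted p = 0.948 for each list with an estimated correlation, 0.82 paired). Paired, the methionine call was lost without replicate 3 or 5 (0.05 and 0.319), and the gluconeogenic one without replicate 2, 3 or 5 (0.204, 0.262 and 0.467). The nitrogen call was lost in that fit without replicate 3 or 5 (0.119 and 0.0932) and the signalling one without replicate 1 (0.0938). Unpaired, the nitrogen call was lost without [BIG+] replicate 3 or 5 (0.0692 and 0.0921). The signalling call was lost there without naive replicate 1 or 2 (0.386 and 0.0873) or [BIG+] replicate 3, 4 or 5 (0.173, 0.0711 and 0.0661). A filter on a mean of at least 10 TPM ended the nitrogen and signalling calls (0.149 and 0.581; paired 0.109 and 0.581) and the paired methionine call (0.0604). The nitrogen call was also lost with the set block and [BIG+] replicate 5 left out (0.0814). Quantile normalization ended the paired gluconeogenic and signalling calls (0.139 and 0.0601), and scaling to nuclear mRNA the gluconeogenic one (0.053). MET6 lost its call without replicate 1, 2, 3, 4 or 5 (adjusted p between 0.0677 and 0.137).

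Cell cycle lists were also lower. Genes of mitotic exit and daughter-cell separation had negative log2 fold changes in 14 of 15 cases, with list means between -0.238 and -0.118 in the 5 pairs. Adjusted over the list alone, 6 of them fell in the paired fit (0 over all genes), including ASH1, a daughter-specific repressor, at -0.289 ± 0.09, and EGT2, a cell separation gene, at -0.309 ± 0.091. G2/M genes were lower in 14 of 14 cases (mean -0.174; 0 past the threshold by either adjustment) and G1/S genes in 21 of 24 (mean -0.133), among which 1, the cyclin gene CLN1, fell when adjusted over the list alone. Camera adjusted p values were 0.0519, 0.0049 and 0.0531 without the block and 0.000883, 0.0043 and 0.0175 with it. The daughter-cell and G1/S calls therefore held only in the paired test (adjusted p = 0.948 for all 3 with an estimated correlation, and 0.68, 0.82 and 0.82 paired). The daughter-cell list was the single list that fry called, in the paired fit (adjusted p = 0.027). The G2/M call was lost without naive replicate 1 (0.243), and the paired G1/S call without replicate 5 (0.0594), with the filter of 10 TPM (0.605) and with quantile normalization (0.0544).

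Camera called 12 lists higher than other genes, by small amounts. Mitochondrial ribosomal protein genes were higher in 47 of 66 cases (mean log2 fold change 0.057; camera adjusted p = 7.72e-06, paired 9.4e-07). With an estimated correlation neither this list nor any of the other 11 named here passed (adjusted p = 0.948 for 10 lists and 0.962 for ribosome biogenesis and chaperones, paired 0.68 for this list and 0.811 to 0.824 for the others). The cytosolic ribosomal protein list, into which the name pattern also took RPP1 of RNase P, was higher in 102 of 135 cases (mean 0.04; 5.05e-08, paired 6.24e-07), but their mean was higher in only 3 of 5 pairs, from -0.332 in pair 2 to 0.371 in pair 5. The direction turned without naive replicate 5 (0.6) and, paired, without replicate 5 (0.888). For ergosterol genes 18 of 24 were higher (mean 0.062; 0.000947), for nuclear respiratory chain genes 25 of 35 (0.047; 0.00193) and for glycolysis and fermentation 12 of 20 (0.053; 0.00255). HXK2, a hexokinase of the last list, rose in the paired fit adjusted over the list alone, at 569 ± 38.9 and 811 ± 99.6 TPM. Camera also called translation factors (0.00277), proteasome subunits (0.0057), ribosome biogenesis (0.00682), amino acid biosynthesis (0.0199), chaperones (0.0247), aminoacyl-tRNA synthetases (0.0322) and subtelomeric PAU and COS genes (0.0333), with list means between -0.001 and 0.036. In the last, COS1, of a family of near-identical copies, rose when adjusted over the list alone (0.691 ± 0.129, paired). No other member of these 12 lists passed in either fit or adjustment. The ribosome biogenesis mean was -0.001 and its median -0.005, below 0 although its test, which compares a list with all other genes (median -0.057), called it higher. For amino acid biosynthesis the median was below 0 (-0.014) and the mean above it (0.002).

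Several of these smaller calls changed with 1 library or pair left out. Without naive replicate 3, 4 or 5 or [BIG+] replicate 1 or 2 ribosome biogenesis did not pass (0.784, 0.363, 1, 0.556 and 0.335), nor did it, paired, without replicate 2 or 5 (0.254 and 0.123). Its direction turned without [BIG+] replicate 1 or 2, and that of chaperones without naive replicate 1 or [BIG+] replicate 5. Chaperones lost their call without naive replicate 1 or 2 or [BIG+] replicate 3 or 5 (0.858, 0.79, 0.459 and 0.868) and, paired, without replicate 2 or 3 (0.155 and 0.108). Synthetases lost it without the same 4 libraries (0.105, 0.79, 0.197 and 0.428) and the same pairs (0.572 and 0.133). Amino acid biosynthesis lost it without naive replicate 1 or 2 or [BIG+] replicate 5 (0.105, 0.541 and 0.133) and, paired, without replicate 1, 2 or 5 (0.0678, 0.914 and 0.0594). The proteasome list did without the same 3 libraries (0.313, 0.136 and 0.455) and, paired, without replicate 2 (0.143). Glycolysis did without naive replicate 1 or 2 (0.13 and 0.0788) and, paired, without replicate 2 (0.0792). Translation factors did without [BIG+] replicate 5 (0.0839) and, paired, replicate 2 (0.135). The respiratory chain call was lost without [BIG+] replicate 4 (0.105) and, paired, replicate 4 (0.115), and the ergosterol call without naive replicate 2 (0.0753). The PAU and COS list lost it without naive replicate 1, 2, 4 or 5 (0.35, 0.164, 0.0555 and 0.0574) or [BIG+] replicate 1, 3 or 4 (0.111, 0.332 and 0.418) and, paired, without replicate 1 or 4 (0.274 and 0.349).

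Processing choices ended calls of the same lists. The filter of 10 TPM did so for ribosome biogenesis (adjusted p = 0.631, paired 0.576), translation factors (0.0999, 0.0923), synthetases (0.403, 0.316), chaperones (0.421, 0.173), proteasome (0.224, 0.094) and amino acid biosynthesis (0.459, 0.581). It did so for the respiratory chain without the block (0.064) and for glycolysis with it (0.109). Quantile normalization did so for translation factors (0.116, paired 0.0829), synthetases (0.324, 0.289), chaperones (0.4, 0.15), amino acid biosynthesis (0.324, 0.474) and the PAU and COS list (0.195, 0.136). It also ended the calls of ribosome biogenesis (0.0741) and the respiratory chain (0.0944) without the block and of glycolysis with it (0.0939). Median-of-ratios scaling ended the PAU and COS call (0.146, paired 0.069) and, without the block, the chaperone call (0.0905). With no filter on low values the PAU and COS call was lost without the block (0.0658). The set block with [BIG+] replicate 5 left out ended the calls of ribosome biogenesis (0.127) and cytosolic ribosomal proteins (0.86).

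In all, camera called 12 lists higher and 8 lower of the 40 tested, and 12 higher and 12 lower with the block. Other splits of the libraries called a median of 11 lists without the block and 11 with it (highest 22 in both). The counts moved to 10 higher and 11 lower with median-of-ratios scaling (11 and 12 paired) and to 5 higher and 9 lower with quantile normalization (6 and 10 paired). Without single libraries the higher lists numbered from 5 (naive replicate 2) to 13, with 6 without naive replicate 1 and 7 without [BIG+] replicate 5, and the lower ones from 6 to 10. Leaving out pairs gave from 5 (replicate 2) to 11 higher and from 6 (replicate 5) to 13 lower. With an estimated correlation 0 lists passed in either fit, and fry called 0 without the block and 1 with it. The other 16 lists had adjusted p values of at least 0.11 (0.0978 paired): pseudouridine synthases, tRNA modification, RNA polymerases I and III, unfolded protein response, TCA cycle, mitochondrial genome, zinc, thiamine, hexose transporters, histones, a-cell genes, pheromone response, meiosis, DNA damage, autophagy and known prion proteins.

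**Figure D3:**
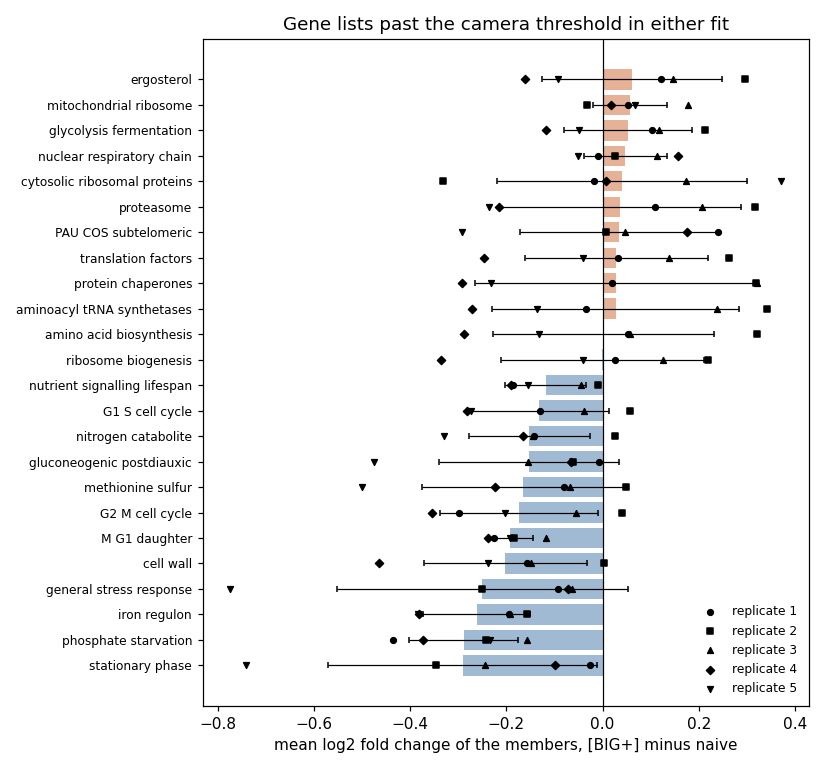
Mean log2 fold change ([BIG+] minus naive, log2(TPM + 1) scale) of the 24 lists called in the paired camera test, as bars, with the SD over the 5 pairs as lines and the single pairs as points. The phosphate, iron, daughter-cell, general stress, stationary-phase, gluconeogenic and nutrient signalling means were lower in 5 of 5 pairs, while the lists above 0 had pairs on both sides of it; the sign of the ribosome biogenesis mean turns with median-of-ratios, mRNA and quantile scaling.

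Small nucleolar RNAs, which guide modification and processing of rRNA, were mostly lower in [BIG+] libraries among those tested. Of 36 tested snoRNAs 30 had negative log2 fold changes (median -0.61), and 25 were lower in all 5 pairs. In the paired fit 13 fell, 9 of 28 tested of box H/ACA and 4 of 5 of box C/D, and without the block 0 fell. Of 45 box C/D RNAs listed only these 5 were tested. The shortest snoRNA tested had 164 nt, against a median of 97 nt for box C/D. Fold change rose with length over 50 small RNAs (Spearman's rho 0.604), so recovery that depends on RNA length may contribute. The box H/ACA RNA snR35 averaged 26030 ± 5850 TPM in naive and 12880 ± 4340 TPM in [BIG+] cells (log2 fold change -1.046 ± 0.187; limma adjusted p = 0.0436, paired). For snR34 the levels were 6112 ± 1860 and 2606 ± 1030 TPM (-1.25 ± 0.205; 0.0316), and for the box C/D RNA snR4 496 ± 211 and 238 ± 86.2 TPM (-1.023 ± 0.108; 0.00412). As a share of all TPM, snoRNAs made up 31.3% ± 3.16 in naive and 25.1% ± 6.1 in [BIG+] libraries (SD, n = 5 each), lower in 5 of 5 pairs by a mean of -6.25 percentage points. A two-sided exact permutation test gave p = 0.0397, which did not pass over the 8 classes (adjusted p = 0.318); within pairs the p was 0.0625, the smallest that 32 assignments allow. Without [BIG+] replicate 5, where snoRNAs held 14.5% and rRNA 17.4%, the difference was -3.6 points. Over the 15 alternatives of the paired fit, adjusted p ran from 0.00685 to 0.22 for snR35, 0.0043 to 0.119 for snR34 and 0.000523 to 0.0327 for snR4.

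No transcript class share passed after adjustment, but a single class could not: the smallest adjusted p it can reach over 8 classes is 0.0635. Messenger RNA made up 47.4% ± 3.65 and 47.3% ± 3.83 of TPM in naive and [BIG+] libraries, and cytosolic ribosomal protein mRNA 16.3% ± 2.49 and 16.6% ± 1.31. The shares in the same order were, for mitochondrial genome mRNA, 0.165% ± 0.045 and 0.17% ± 0.0356, for snRNA, 3.47% ± 0.291 and 3.39% ± 0.797, and for other non-coding RNA, 16.9% ± 2.9 and 20.2% ± 4.68. The 10 most abundant features held 43.8% ± 3.47 and 42.2% ± 9.39. Exact permutation p values were at least 0.222 for each of these classes, and adjusted p values at least 0.888. The rRNA share was 0.944% ± 0.429 in naive and 4.15% ± 7.42 in [BIG+] libraries, where 17.4% in replicate 5 set the mean (exact permutation p = 0.579, adjusted p = 0.952).

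**Figure D4:**
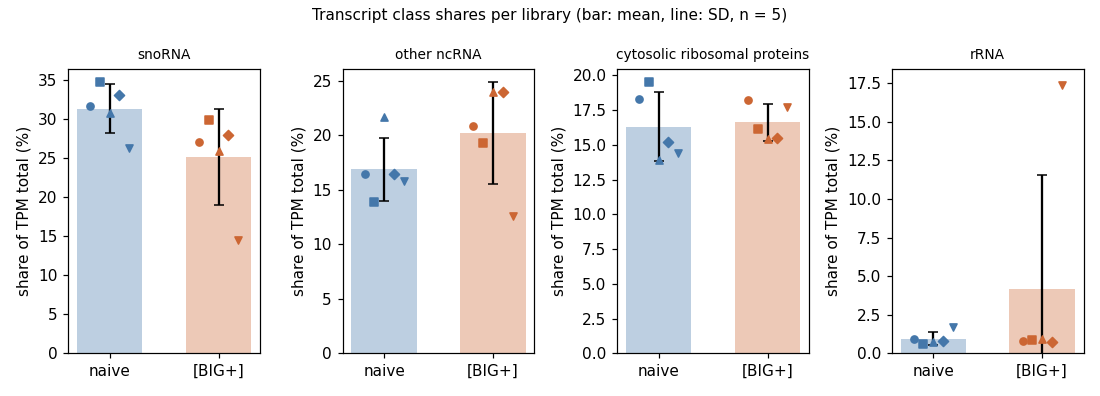
Percent of library TPM held by snoRNA, other non-coding RNA, cytosolic ribosomal protein mRNA and rRNA, 1 point per library, with the mean of each state as a bar and the SD as a line (n = 5), cut off at 0 for rRNA in [BIG+]. The snoRNA share was lower in [BIG+] in 5 of 5 pairs, and [BIG+] replicate 5 stood apart with 17.4% rRNA and 14.5% snoRNA.

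In the paired fit 2 features rose, and a small open reading frame was among those that fell. The mitochondrial small-subunit 15S rRNA (Q0020, mitochondrial genome, 6546 to 8194) averaged 45.5 ± 15.7 TPM in naive and 134 ± 83.8 TPM in [BIG+] libraries. It was higher in 5 of 5 pairs. Its log2 fold change was 1.44 ± 0.252 (limma adjusted p = 0.041; 0.00441 to 0.264 over 15 alternatives), and [BIG+] replicate 5 held 281.7 TPM. As rRNA was depleted, a difference in the rRNA left over cannot be told apart from a change in the cells. The rDNA feature RDN37 was also higher in 5 of 5 pairs. It was at 88.36 to 149.9 TPM in naive and 185.4 to 9827 TPM in [BIG+] libraries. YLR154W-E, a reading frame of the rDNA region, was higher in pairs 1 to 4 and lower in pair 5. The rDNA features ITS1 and ETS2 were lower in pairs 1, 2, 3 and 5, and ETS1 and ITS2 went both ways. YHR054C (chromosome VIII, 213185 to 214249), inside the repeated CUP1 region, averaged 7.07 ± 2.64 and 13.2 ± 3.33 TPM (0.844 ± 0.117; 0.0139, 0.00263 to 0.0601 over 15 alternatives). Copies of this repeat can share reads, so its value is uncertain. YCL048W-A, of unknown function (chromosome III, 41488 to 41727), averaged 15.2 ± 5.52 and 5.52 ± 0.957 TPM (-1.26 ± 0.163; 0.0116, 0.00219 to 0.0491 over 15 alternatives). With a pseudocount of 10 the log2 fold changes were 0.445 for YHR054C and -0.674 for YCL048W-A. The 15S rRNA did not pass without replicate 2, 3 or 4 (0.112, 0.124 and 0.13), nor YHR054C without replicate 1 or 2 (0.0601 and 0.0541).

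PUS4, a pseudouridine synthase gene that the study ties to this prion, showed no difference in transcript level beyond the spread between replicates. The transcript (YNL292W, chromosome XIV, 82806 to 84017) averaged 6.09 ± 1.75 TPM in naive and 6.32 ± 2.12 TPM in [BIG+] cells (SD, n = 5 each), a log2 fold change of 0.031 (two-sided exact permutation p = 0.905, adjusted p = 0.952; 0.875 within pairs). CBF5, the pseudouridine synthase of box H/ACA complexes, averaged 29.6 ± 7.57 and 33.1 ± 12.1 TPM, and PUS7 10.4 ± 2.56 and 11 ± 2.54 TPM. None of the 11 genes tested in this family of pseudouridine synthases and HIS3 passed, and their adjusted p values were at least 0.941 (0.0873 is the smallest that a single changed gene can reach). In limma, PUS4 had an adjusted p of 0.999 (0.936 paired). The sign of the PUS4 difference turned without naive replicate 2 or 3 (-0.0195 and -0.0409) or [BIG+] replicate 2 or 5 (-0.0022 and -0.116).

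Marker genes of the BY4741 background were compared as a check of the strain. LEU2, MET17 and URA3 were listed at 0 in all 10 libraries. HIS3, which carries a partial deletion in the textbook genotype of this strain, averaged 31.4 ± 12.2 TPM in naive and 28.4 ± 15 TPM in [BIG+] cells (exact permutation p = 0.595, 0.125 within pairs). The mating type a receptor gene STE2 averaged 286 ± 55.5 and 306 ± 33.3 TPM, while SAG1, an alpha-cell gene, averaged 2.13 ± 0.691 and 1.60 ± 0.184 TPM.

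Chromosome medians lay close together in both states. Group differences in the chromosome medians ran from -0.038 to 0.01 on the log2 scale (smallest adjusted p = 0.838, exact permutation, where a chromosome shifted alone can reach 0.127 at best). An extra copy in all haploid cultures of 1 state would shift this difference by 1. Single libraries, each taken against the mean of all libraries, ran from -0.077 to 0.106. An extra copy shared by all libraries would not show in these values.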

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

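The tests of the rRNA pattern below were chosen after the result was seen. A value was picked out where 1 library of a group of 5 lay far from the other 4, by a gap above 0.71 of the group's range. Chance does so for about 1 in 20 groups, 11 of the 218 examined; 22 were found, 9 of them in [BIG+] replicate 5 and 12 in naive replicate 5.

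In [BIG+] replicate 5, rRNA held 17.4% of TPM against 0.729 to 0.951% in the other 4 [BIG+] libraries. The features RDN25 and RDN18 were at 38140 and 32940 TPM there and listed at 0 in the other 9 libraries. A shift of the same reads among the overlapping rDNA features with a known length is argued against as the whole cause. Their length-weighted sum was 38.4 times the highest of the other 9 libraries. With YLR154W-E, a reading frame of the rDNA region without a known length, counted at 6858 nt, the longest rDNA feature, it was 7.25 times. That lies between the bounds set for and against such a shift, so a shift that includes YLR154W-E cannot be judged. Reads assigned to no feature are not in these sums. For a part of the reads such a shift may contribute: YLR154W-E was at 10.64 TPM in this library against 3771 to 9301 in the other 9, a ratio of 0.00282 to the lowest. Less complete removal of rRNA from that library may also contribute: the mitochondrial 21S rRNA, a separate transcript, stood at 644 times the highest of the other libraries. The other mitochondrial rRNA, 15S, differed far less, at 281.7 TPM against 29.1 to 113.4 in the other 9. A read filter applied to the other 9 libraries was not tested and stays open. The prion state alone does not set this level, since the 4 other [BIG+] libraries lack it.

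Other shares stood apart in the same library: snoRNA at 14.5% (others 25.9 to 29.9%), snRNA at 1.97% (3.67 to 3.86%) and the 10 most abundant features at 25.6% (44.4 to 48.5%). In naive replicate 5, rRNA held 1.69% (0.609 to 0.918%). Chromosome medians that stood apart were -0.0213 for chromosome 4 and 0.0216 for chromosome 14 in naive replicate 5, and 0.0201 for chromosome 8 in [BIG+] replicate 1.

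Single genes that stood apart in [BIG+] replicate 5 were HIS3 at 55 TPM (others 18.4 to 23.9), the 15S rRNA at 281.7 (79.8 to 113.4), TRM112 at 120.4 (42.6 to 60.9), MET6 at 124 (36.7 to 58.5) and CWP2 at 5279.2 (1749.4 to 2240.3). In naive replicate 5 they were YGP1 at 144.6 TPM (81.6 to 94.3), SSA2 at 2074.8 (648 to 1044.9), MET6 at 213.6 (50.2 to 77.6), UGA1 at 50.4 (25 to 30.3), SMK1 at 5.85 (2.69 to 3.52), RNR2 at 561.4 (300.5 to 375.5), SUP35 at 81.3 (32.6 to 46.1), NCA3 at 8.65 (4.66 to 5.38) and PNS1 at 35.6 (12.3 to 16).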

How the results depend on the processing

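Alternatives to the paired fit, the block by replicate sets and the fits without [BIG+] replicate 5 were chosen after seeing the data; the others were planned. The cause of each change below was not tested unless it is named. Sequencing depth is unknown, so its limits cannot be given.

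Genes: without a block limma called 0 higher and 0 lower, and 0 of each without any single library. A mean filter of 10 TPM gave 1 lower gene, GSC2; median-of-ratios and quantile scaling gave 3 lower, NCA3, SPS100 and YCL048W-A in both; nuclear mRNA scaling gave 3 lower, SPS100, YCL048W-A and GSC2. The replicate block gave 2 higher and 33 lower, the set block 3 and 40 (33 of the 35 paired calls among them), and the set block with [BIG+] replicate 5 left out 17 and 35. In the paired fit, 6 were higher with the filter of 10 TPM and 1 with median-of-ratios scaling, quantile normalization or a fold threshold of 1 (log2). Lower were 48 with the filter of 10 TPM, 47 with robust eBayes, 15 with no filter, 13 with median-of-ratios scaling, 17 with quantile normalization and 6 with the fold threshold. Of the 35 paired calls, 26 were among the 54 made with the filter of 10 TPM and 34 among the 49 with robust eBayes. Leaving out 1 pair, which also removes 2 libraries, gave 1 to 9 higher and 8 to 26 lower, and kept between 9 and 23 of the 35 calls.

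Lists: 12 higher and 8 lower became 5 and 4 with the filter of 10 TPM, which leaves fewer genes, 5 higher with quantile normalization, and 0 and 0 with an estimated correlation or fry. Single libraries left out gave 5 to 13 higher. With the replicate block, 12 and 12 became 5 and 5 with that filter, 6 higher with quantile normalization, 0 and 0 with an estimated correlation and 0 and 1 with fry; pairs left out gave 5 to 11 higher and 6 to 13 lower. Direction turned for cytosolic ribosomal proteins with the set block and [BIG+] replicate 5 left out (adjusted p = 0.86; 3.13e-26 to 0.6 over the left-out libraries, and 7.3e-29 to 0.888 over left-out pairs with the replicate block). It turned for ribosome biogenesis with fry (0.998, and 0.999 with the replicate block; 4.96e-11 to 1 over left-out libraries), for amino acid biosynthesis with fry and the replicate block (0.999), and for chaperones (1.01e-05 to 0.868 over left-out libraries). The turns came without naive replicate 5 (paired, replicate 5) for cytosolic ribosomal proteins, without [BIG+] replicate 1 or 2 for ribosome biogenesis (0.556 and 0.335), and without naive replicate 1 or [BIG+] replicate 5 for chaperones (0.858 and 0.868).

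The PUS4 difference ran from -0.116 (without [BIG+] replicate 5) to 0.166 (without naive replicate 5), and exact permutation adjusted p values stayed at or above 0.829 over its alternatives. The filter of 10 TPM leaves out PUS4, and dropping the filter changes nothing there, so neither has a value. The snoRNA share stayed lower under every alternative run, by -7.5 to -3.6 percentage points without single libraries. For classes and chromosomes the exact test is too coarse for a single one to pass, so the absence of calls under these alternatives shows no stability. The block also changed which list members passed when adjusted over the list alone. Among others, 1 and 10 general stress genes fell without and with it, 1 and 7 phosphate genes, 0 and 10 iron genes and 1 and 4 cell wall genes.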

Other observations

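Of the tests below, those of the snoRNAs and of the lower mRNAs without pair 5 were chosen after the result was seen, and the set block was too; the counts over other splits and the comparison of lower mRNAs with the differences between replicate sets were written before it.

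The libraries differed by replicate number in whole gene groups. In the 2 samples numbered 5, all 29 chaperone genes were higher than in the other 8 samples (mean difference 1.45 on the log2 scale), as were 41 of 45 general stress genes (1.0), 33 of 33 proteasome genes (0.83) and 17 of 17 TCA cycle genes (0.74), while hexose transporters averaged -0.56. Taken by state, general stress genes differed by 1.33 in naive and 0.67 in [BIG+] libraries, and chaperones by 1.61 and 1.29. Between the 4 samples numbered 3 and 4 and the 4 numbered 1 and 2, ribosome biogenesis genes differed by -0.88 (1 of 134 higher), histones by -0.87 (0 of 10), hexose transporters by -0.76 and daughter-cell genes by -0.61. These samples were set apart from the data, so no test is given.

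The metallothionein gene CUP1, a cluster of identical copies, varied across these sets too. Its copies were each at 156.5, 133.5, 729.6, 767.7 and 60 TPM in naive libraries 1 to 5 and at 551.1, 396.2, 1131, 999.8 and 41.2 TPM in [BIG+] libraries 1 to 5. It was higher in [BIG+] in pairs 1 to 4 and lower in pair 5.

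Other splits of the samples were counted for each result. Without a block the real split called 0 genes, a count that all 100 of 100 drawn splits reach by definition, so this says nothing about chance. At an unadjusted p under 0.05, 56 of the 100 gave at least the real 96 genes. The highest other split called 684 genes past the threshold, which points to a structure of the samples, since it parts naive 1, 2 and 5 and [BIG+] 1 and 2 from the rest. Of 100 splits, 4, the real one included, called at least as many lists as the real 20 (highest other 22, median of the others 11). That is a share under 0.05 over all splits. Most of these splits break the pairs, unlike the real one, so the share does not exclude chance. The 14 that part all 5 pairs are too few for such a share (real 20, highest other 19). With the replicate block 16 splits are too few for such a share: 1 gave as many genes (real 35, highest other 1) and 1 as many lists (real 24, highest other 22). With the set block 1 of 36 splits, the real one, gave as many genes (real 43, highest other 1). Likewise 1 of 36 gave as many lists (real 24, highest other 22, median of the others 10). Both shares lie under 0.05, but the sets were read off these same data, so chance is not excluded. At an unadjusted p under 0.05, 5 of the 36, the real one included, gave at least the real 675 genes (highest other 1084). In the replicate block another of the 16 gave 698 against the real 650. Of these 36, 16 part all 5 pairs, again too few (highest other 1 gene and 22 lists).

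The first pattern weighed is the lower level of snoRNAs in [BIG+] libraries. The rRNA-rich library [BIG+] replicate 5 is argued against as its whole cause, because the median log2 fold change of the 36 tested snoRNAs was -0.535 without pair 5. Recovery that depends on RNA length may contribute: over 50 small RNAs, fold change rose with length (Spearman's rho 0.604 across RNAs, which are not independent replicates; permutation p = 3e-05). Over snoRNAs alone rho was 0.353 (p = 0.035). Whether box H/ACA guides changed more than box C/D guides cannot be told apart, since the medians differed by 0.136 (exact permutation p = 0.373) and only 5 C/D RNAs were tested. An effect of the prion state on snoRNAs stays open and was not tested apart from RNA length or from other differences between the strains.

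The second pattern is the lower level of 20 mRNAs in the paired fit. It is not fully separate from the first, since YGL088W, 1 of the 20, overlaps snR10. Their log2 fold changes were -0.772 and -0.824, so the value of YGL088W may come from the snoRNA. IRC9 and SPS100 overlap other genes too. YAL016C-B, at a mean of 1.77 TPM in naive and 0.603 TPM in [BIG+] libraries, and YDR445C had no match in the R64 reference. [BIG+] replicate 5 is argued against as their whole cause, because a paired fit without replicate 5, which picks its genes anew, called 14 mRNAs lower. Of these, 11 were among the 20, and each other split of the 4 pairs (8 splits in all, the real one included) called at most 1 mRNA in either direction. A difference like the one that separates the replicate sets cannot be told apart from the prion state. Of the 20 mRNAs, 80% lay on 1 side of the axis between replicates 3 and 4 and replicates 1 and 2 (4 higher, 16 lower), between the bounds set for and against it. That share weighs little, since only 33.5% of all tested genes were higher on this axis. On the axis between replicate 5 and replicates 1 and 2 the 20 mRNAs were split, 11 higher and 9 lower, where 72.5% of all tested genes were higher. An effect of the prion state on these mRNAs stays open. It was not tested apart from the replicate sets or from other differences between the strains.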
